A study of Mus musculus with 9 samples.

How the data were processed

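RNA sequencing had been carried out on cells sorted by fluorescence from mouse brain at postnatal day 60, with 9 libraries in 3 groups of 3. The groups are named here by the reporter of the sort: PDGFRa-GFP, PLP-GFP and NDRG1-eGFP, which the labels call oligodendrocyte progenitors, pre-myelinating oligodendrocytes and myelinating oligodendrocytes. Per the labels' protocols, total RNA and DNA were isolated from the same cell pellets with a column kit and libraries were prepared by standard Illumina procedures. The submitters' processing notes name BWA, DESeq2 1.2.5 and the mouse genome build mm10, without saying what each was used for.

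Each deposited file gave 1 library, with a gene symbol and a normalized value, per the file headers, for the same 11315 genes. The values had been put on a log2 scale by the authors before deposit: they ran from 0.29 to 21.87 in every library (lowest value 0.32 in some), with medians of 10.57, and the sorted values were nearly identical between libraries, as after quantile normalization. The order of genes within a library therefore carries the information. Raw read counts were not analysed here, so sequencing depth is unknown. Tied values showed how many distinct values each library held before the transformation: 5207, 5007 and 4454 in the PDGFRa-GFP libraries, 4859, 5473 and 5308 in the PLP-GFP libraries, and 5422, 4837 and 5584 in the NDRG1-eGFP libraries. In 17 rows the symbol had been turned into a date by a spreadsheet, and these rows were not named.

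The test planned for normalized values was limma-trend on log2(value + 1). Because the deposited values were already logarithms, limma-trend (limma 3.58.1 in R 4.3.3) was fitted to them as they stand, with no added constant, all 9 libraries in 1 fit with a term per group. Genes with a value of at least 1 in at least 3 libraries were kept, which removed none. The 3 comparisons were NDRG1-eGFP against PLP-GFP, PLP-GFP against PDGFRa-GFP and NDRG1-eGFP against PDGFRa-GFP. P-values were adjusted by the Benjamini-Hochberg method over all genes, and an adjusted p under 0.05 was called. Log2 fold changes are the first group minus the second, with the standard error of the fit. Tests were two-sided. With 3 libraries against 3, an exact permutation test of a single gene could not give p under 0.1, so no such test was used.

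Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. There were 25 lists, and 24 had at least 5 measured members. They covered oligodendrocyte progenitor markers, newly formed oligodendrocyte markers, myelin sheath proteins, markers of mature oligodendrocyte states, oligodendrocyte transcription factors, cholesterol synthesis, fatty acid and sphingolipid synthesis, the cell cycle, ion channels and transmitter receptors, inhibitors of differentiation from the Notch, BMP and Wnt pathways, chromatin enzymes, actin assembly, actin disassembly, hypoxia response, glycolysis, oxidative phosphorylation, MHC with complement and interferon genes, immediate early and dissociation stress genes, and markers of neurons, astrocytes, microglia, endothelium, pericytes, fibroblast-like cells and ependyma.

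Named genes were chosen by a rule fixed before the data were examined. They were the reporter genes, the 10 highest and 10 lowest log2 fold changes per comparison, up to 4 members of each list with the smallest adjusted p, Y-linked genes, and 5 genes for each pattern over both steps. The extreme genes had to be called, to reach 10 parts in 1e+06 of the summed linear values in the higher group (in place of the planned limit on counts), and to have libraries that did not overlap between the groups. Predicted genes and pseudogenes were passed over.

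Transcript lengths and shared sequence came from GENCODE M21 on GRCm38, the assembly that mm10 denotes. For each gene the share of its 50-base transcript windows that also occur in transcripts of another locus was computed. Of the 11315 symbols, 11271 had an annotation, directly or through an older symbol. A gene with over 5 percent shared windows is called shared here, and its value is uncertain, since reads could be split between copies.

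Alternatives named before the data were examined were recentring by the median ratio (also without the myelin list and the 20 most abundant genes) or the upper quartile, no filter, added constants of 0.1 and 5 on the linear scale, a replicate block, fits of only the groups compared, an absolute log2 fold change of at least 1, an adjusted p under 0.01, fry, and leaving out each library. Alternatives chosen after the data were seen removed each library's trend on transcript length, left out shared genes, did both, kept genes with a mean of at least 8, left out 2 libraries together, or used robust empirical Bayes. The fit was tested on simulated data for each comparison over 11315 genes with 200 changed. For NDRG1-eGFP against PLP-GFP it recovered 87.0% of 4-fold and 59.0% of 2-fold changes. The shares were 89.0% and 57.0% for PLP-GFP against PDGFRa-GFP, and 91.0% and 67.0% for NDRG1-eGFP against PDGFRa-GFP. False calls were 9 of 155, 5 of 151 and 7 of 165 calls in the same order. The data differ from this setting, with 5460 genes called for NDRG1-eGFP against PLP-GFP, so these shares may not hold for them.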

Results

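The series compared gene expression between mouse brain cells sorted with 3 fluorescent reporters at postnatal day 60, and its title concerns a myelinating oligodendroglial population that expresses NDRG1. There were 3 libraries each for PDGFRa-GFP, PLP-GFP and NDRG1-eGFP cells, with normalized log2 values for 11315 genes. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries only. Y-linked genes, given below, differed between libraries of 1 group. Pearson correlations between libraries of 1 group ran from 0.931 to 0.982 for PDGFRa-GFP, from 0.975 to 0.985 for PLP-GFP and from 0.939 to 0.964 for NDRG1-eGFP. PLP-GFP and NDRG1-eGFP libraries correlated at 0.876 to 0.894. PDGFRa-GFP libraries correlated with PLP-GFP libraries at 0.912 to 0.932 and with NDRG1-eGFP libraries at 0.881 to 0.925. The highest of these values lay just above the lowest within the PDGFRa-GFP group. There, replicate 3 correlated with replicates 1 and 2 at 0.935 and 0.931, and replicates 1 and 2 with each other at 0.982.

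The reporter genes were examined first. Pdgfra, the growth factor receptor of oligodendrocyte progenitors and of fibroblasts (chromosome 5, 75152292 to 75198215, GRCm38), averaged 6.63 ± 1.05 (SD, n = 3) in PDGFRa-GFP libraries, 2.71 ± 1.96 in PLP-GFP libraries and 5.70 ± 0.65 in NDRG1-eGFP libraries. These means lay below the median of all genes, 10.57. Ndrg1 (chromosome 15, 66929318 to 66969640) averaged 16.80 ± 0.06, 16.84 ± 0.14 and 16.99 ± 0.06 and was not called in any comparison (limma adjusted p of 0.301, 0.833 and 0.256). The 27 measured myelin genes had a median of 16.57 to 16.64 in PDGFRa-GFP libraries, 16.63 to 16.73 in PLP-GFP libraries and 16.63 to 16.68 in NDRG1-eGFP libraries, and made up 11.8% to 14.5% of the summed linear values. The 16 measured progenitor markers had library medians between 6.17 and 8.18. The libraries labelled as progenitors thus held myelin transcripts at the level of the other groups, and directions below are given by reporter.

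**Figure D1:**
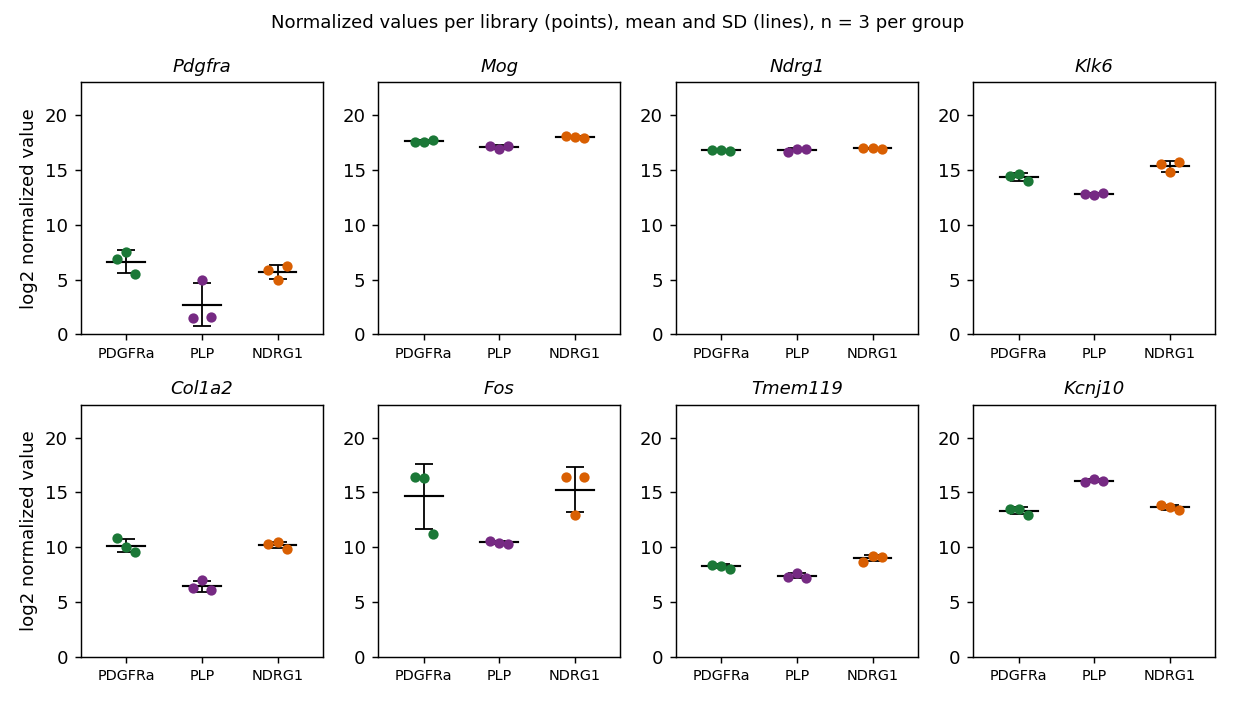
Deposited log2 normalized values (vertical axis) of 8 genes in each library (points), with the group mean and SD (lines, n = 3), for the 3 sorted groups (horizontal axis). Pdgfra sits at 2.71 to 6.63 on average, Mog at 17.08 to 18.02, and Col1a2 at 6.45 in PLP-GFP against 10.16 and 10.21 in the PDGFRa-GFP and NDRG1-eGFP groups.

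The comparison of NDRG1-eGFP with PLP-GFP cells asks what sets the NDRG1 population apart from the cells labelled pre-myelinating. Several genes of mature oligodendrocytes were higher in NDRG1-eGFP cells. Klk6, a secreted protease of mature oligodendrocytes, had a log2 fold change of 2.53 ± 0.24 (SE, n = 3), and the myelin genes Opalin (1.13 ± 0.18) and Mog (0.94 ± 0.13) rose less. The inhibitors of differentiation Id1 (3.66 ± 0.34) and Id2 (2.50 ± 0.28) were also higher. Lower were Myrf, a transcription factor required for myelination (-1.30 ± 0.18), Etv5 (-2.13 ± 0.26, shared), the potassium channel gene Kcnj10 (-2.41 ± 0.18) and the pacemaker channel gene Hcn2 (-2.38 ± 0.35). Of the fatty acid synthesis enzymes, Acaca (-2.51 ± 0.32, shared) and Fasn (-0.94 ± 0.20) were lower and the elongase gene Elovl1 (1.15 ± 0.13) was higher.

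Of 11315 genes, 2953 were higher and 2507 lower in NDRG1-eGFP than in PLP-GFP cells (limma), against 2555 and 2789 after recentring on the median ratio. With the length trend described below removed, 1798 were higher and 1978 lower, and 2960 of the 5435 earlier calls among the genes with a length kept their call and direction. Fasn had a log2 fold change of -0.35 in that fit and was not called, and Mog had 0.35.

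The markers of mature oligodendrocyte states moved up as a list, with 13 of 24 measured members higher and 2 lower (13 and 2 adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.871 with an estimated correlation). Among them were the annexin gene Anxa5 (1.44 ± 0.16) and the peripheral myelin gene Pmp22 (1.03 ± 0.14). Cholesterol synthesis rose in 11 of 20 enzymes and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.871 with an estimated correlation), with Mvk at 1.67 ± 0.23 and Mvd at 1.44 ± 0.20. The enzyme that fell was Idi1 (-2.69 ± 0.18), of which 17.7% of windows were shared. Oxidative phosphorylation subunits rose in 22 of 28 and fell in 1 (22 and 1 adjusted over the list alone; camera adjusted p = 0.00134, and adjusted p = 0.871 with an estimated correlation), as in Ndufa10 (1.04 ± 0.13) and Cyc1 (1.03 ± 0.15). After removal of the length trend 4 rose and 4 fell, and the median went from 0.69 to 0.13. The subunit that fell as deposited was cytochrome c, Cycs (-3.12 ± 0.22, 26.1% shared). Ion channels and transmitter receptors fell as a list, although 5 of 17 fell and 3 rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.0370, and adjusted p = 0.871 with an estimated correlation).

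Markers of other cell types and the immediate early and dissociation stress genes also separated these groups, and the cause was not tested. Fibroblast-like and meningeal markers were higher in 10 of 11 measured members (10 adjusted over the list alone; camera adjusted p = 0.00134, and adjusted p = 0.871 with an estimated correlation), including the collagen genes Col1a1 (4.31 ± 0.77) and Col1a2 (3.76 ± 0.35). Among the 10 highest fold changes that met the naming rule were Mgp, a matrix Gla protein gene (6.52 ± 0.67), the transporter gene Slc47a1 (6.08 ± 0.73), Fxyd5 (5.74 ± 0.58), Penk (5.66 ± 0.67), Efemp1 (5.31 ± 0.34) and Emb (4.88 ± 0.69). Microglial markers were higher in 11 of 16 (12 adjusted over the list alone; camera adjusted p = 0.00134, and adjusted p = 0.871 with an estimated correlation), such as Tmem119 (1.60 ± 0.24) and P2ry12 (1.88 ± 0.34). MHC, complement and interferon genes were higher in 12 of 20 (12 adjusted over the list alone; camera adjusted p = 0.00901, and adjusted p = 0.871 with an estimated correlation), with the MHC class II chaperone gene Cd74 at 2.65 ± 0.39. Immediate early and dissociation stress genes were higher in 16 of 22 (16 adjusted over the list alone; camera adjusted p = 0.00299, and adjusted p = 0.871 with an estimated correlation). Fos averaged 15.25 ± 2.03 (SD, n = 3) against 10.43 ± 0.14, and Egr2 11.16 ± 2.04 against 5.96 ± 0.64. The library medians of the immediate early list were 11.84, 10.14 and 12.48 in NDRG1-eGFP replicates 1, 2 and 3 and 9.24 to 9.48 in PLP-GFP libraries. Egr2 was no longer called in 5 of the 6 fits that left out a library.

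None of the 8 list calls held with an estimated correlation. With the length trend removed, the calls of the mature state list (camera adjusted p = 0.479), the oxidative phosphorylation list (0.708) and the ion channel list (0.519) were lost. Over all alternatives with the preset correlation these p-values ran from 0.00725 to 0.714, from 2.26e-04 to 0.708 and from 0.0182 to 0.519. Those of the cholesterol, immediate early, microglial and fibroblast-like lists stayed at or below 0.0468, 0.0435, 0.0328 and 0.0116, and those of the MHC, complement and interferon list ran from 8.81e-04 to 0.129.

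The remaining 16 tested lists had camera adjusted p-values from 0.376 to 0.976 in this comparison. Myelin sheath genes rose in 9 of 27 and fell in 4, against 3 and 5 with the length trend removed. Oligodendrocyte transcription factors rose in 4 of 15 and fell in 4, and newly formed oligodendrocyte markers rose in 5 of 23 and fell in 5. Among progenitor markers Pdgfra rose (2.99, from 2.71 ± 1.96 to 5.70 ± 0.65, mean and SD, n = 3) and Matn4 fell (-1.26 ± 0.46), of 16 measured, and these calls were lost in 4 and 3 of the 6 fits that left out a library. Fatty acid and sphingolipid enzymes rose in 8 of 26 and fell in 5, and chromatin enzymes rose in 5 of 25 and fell in 8, with the methyltransferase cofactor Suz12 at -1.36 ± 0.16. Actin assembly genes rose in 7 of 21 and fell in 8, with Actr2 of the Arp2/3 complex at -1.54 ± 0.15 and Wasf3 at -1.81 ± 0.22, and actin disassembly genes rose in 4 of 12 and fell in 4, with the actin severing gene Gsn at 1.11 ± 0.17 and the cofilin phosphatase gene Ssh3 at -3.15 ± 0.43. Glycolysis genes rose in 5 of 22 and fell in 8, hypoxia response genes rose in 3 of 19 and fell in 7, pathway inhibitors of differentiation rose in 5 of 19 and fell in 6, and cell cycle genes rose in 2 of 12 and fell in 3. Astrocyte markers rose in 3 of 18 and fell in 1, endothelial markers rose in 1 of 5, and 1 of 9 ependymal markers fell. None of the 11 neuron markers or the 4 pericyte markers passed limma's adjusted threshold. Adjusted over the list alone the counts differed for the progenitor list (0 and 0), the newly formed list (5 rose and 4 fell), the pathway inhibitors (5 and 7), actin disassembly (5 and 4) and the ependymal list (0 and 0).

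The genes with the lowest fold changes in NDRG1-eGFP cells that met the naming rule, all but 1, had near-identical copies elsewhere and are uncertain. They were the alpha globin gene Hba-a1 (-11.61 ± 0.87), the tubulin gene Tuba1b (-7.95 ± 0.40), the ubiquitin gene Ubb (-7.42 ± 0.22), the ribosomal protein genes Rpl24 (-6.63 ± 0.28), Rps23 (-6.53 ± 0.35) and Rpl9 (-6.31 ± 0.32), and the mitochondrial genes mt-Co2 (-8.35 ± 0.34), mt-Atp6 (-7.46 ± 0.41) and mt-Co3 (-6.34 ± 0.45). Their shared windows ranged from 18.5% in Rpl9 to 100% in mt-Co2. Also among these was mt-Atp8 (-8.54 ± 0.42), which had no shared window but is a short gene that overlaps mt-Atp6. Hba-a2 (5.53 ± 1.06) and the MHC class I gene H2-T10 (5.36 ± 0.67), among the 10 highest, were also shared, in 89.3% and 33.3% of windows. Gapdh (-2.81 ± 0.13), Pgk1 (-3.03 ± 0.19) and Pgam1 (-3.41 ± 0.20), which were among the glycolysis genes that fell, were shared in 24.7%, 53.9% and 36.2% of windows.

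**Figure D2:**
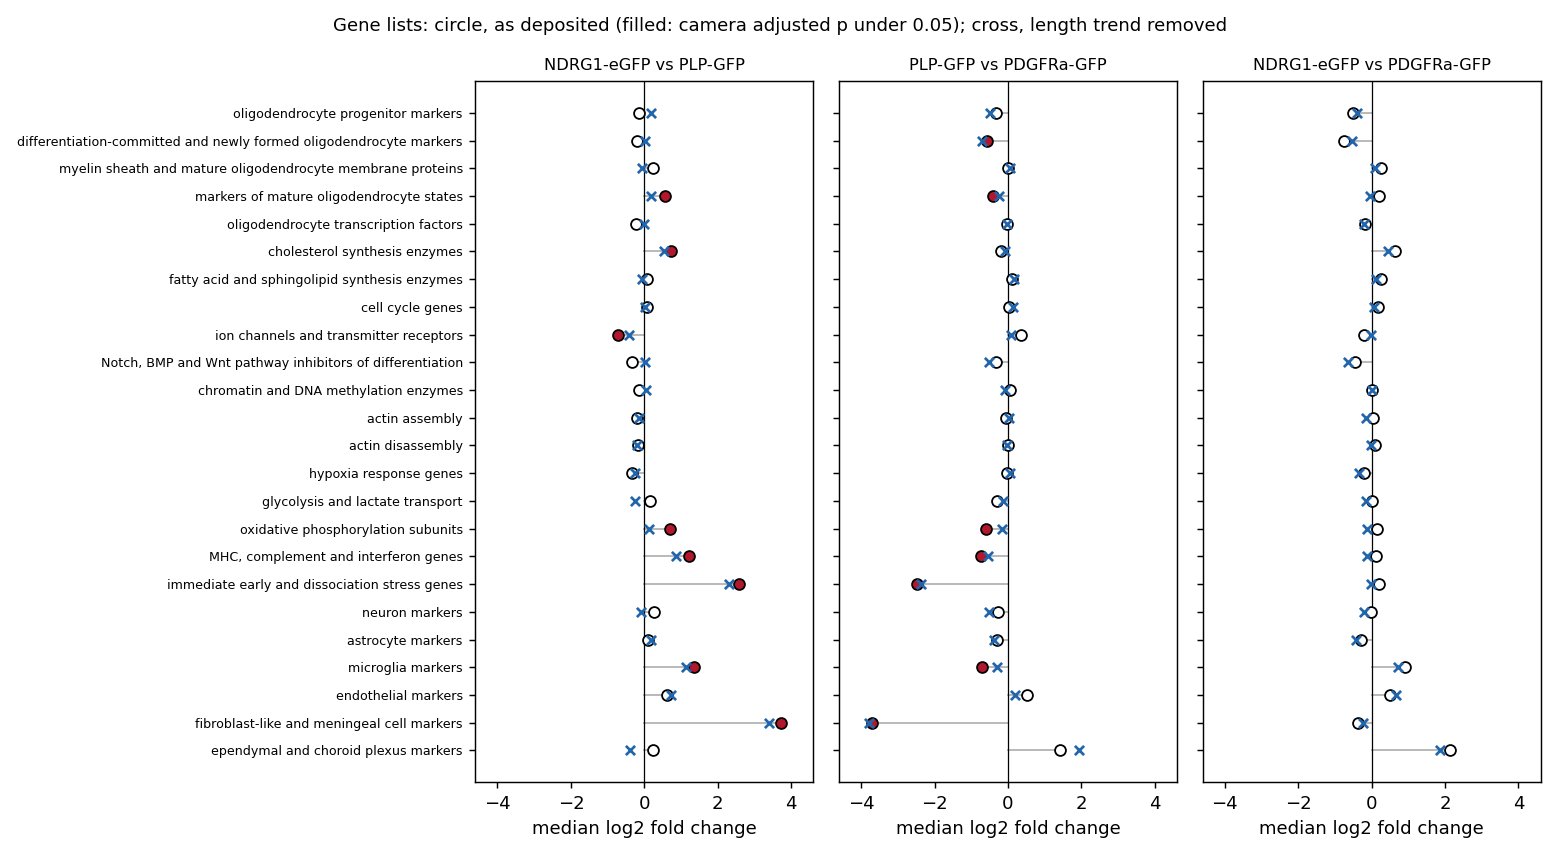
Median log2 fold change (horizontal axis) of each tested gene list (rows) in the 3 comparisons, as deposited (circles, filled where camera's adjusted p was under 0.05) and with the length trend removed (crosses). The fibroblast-like list lies at 3.72 in NDRG1-eGFP against PLP-GFP and at -3.71 in PLP-GFP against PDGFRa-GFP, and at -0.36 in NDRG1-eGFP against PDGFRa-GFP.

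PLP-GFP was compared with PDGFRa-GFP to follow the step from cells labelled progenitors to cells labelled pre-myelinating. Kcnj10, which encodes an inwardly rectifying potassium channel, was higher in PLP-GFP cells (2.76 ± 0.18, SE, n = 3), as was Etv5 (1.34 ± 0.26, shared). Pdgfra was lower (-3.92, limma adjusted p = 0.0274), as were Bmp4, a marker of newly formed oligodendrocytes (-4.17 ± 0.78), Sox4 (-2.27 ± 0.48), Id1 (-2.97 ± 0.34), Id2 (-2.61 ± 0.28) and Id3 (-1.31 ± 0.22). Besides Kcnj10, the highest fold changes in PLP-GFP cells that met the naming rule, with its minimum level, belonged to Fcho1, a gene of clathrin-mediated endocytosis (7.22 ± 1.06), the peroxidasin gene Pxdn (3.67 ± 0.43), Dlk2 (3.63 ± 0.38), the protocadherin gene Pcdhga4 (3.15 ± 0.37), Zrsr1 (3.07 ± 0.18), Gstcd (2.82 ± 0.38), Scrg1 (2.69 ± 0.58), Galnt10 (2.58 ± 0.20) and Stk10 (2.46 ± 0.26). The call of Pdgfra was lost in 4 of the 6 fits that left out a library, where its log2 fold change lay between -5.05 and -3.32.

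In all, 957 genes were higher and 965 lower in PLP-GFP than in PDGFRa-GFP cells (limma), against 863 and 1101 after recentring on the median ratio. With the length trend removed, 402 were higher and 646 lower, and 845 of the 1917 calls among genes with a length kept their call and direction. The count depended on single libraries. The numbers higher were 92, 144 and 604 without PLP-GFP replicate 2, 3 and 1, and 376 and 1449 without PDGFRa-GFP replicate 2 and 3. The numbers lower were 186 and 225 without PLP-GFP replicate 2 and 3, and 383 without PDGFRa-GFP replicate 2.

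Fibroblast-like markers were lower in PLP-GFP cells in 10 of 11 members (10 adjusted over the list alone; camera adjusted p = 1.03e-07, and adjusted p = 0.473 with an estimated correlation). Col1a1 was lower by -5.58 ± 0.77 and Col1a2 by -3.71 ± 0.35 in log2 fold change, and the other lowest fold changes that met the naming rule belonged to Mgp (-6.94 ± 0.67), Slc47a1 (-6.72 ± 0.73), Fxyd5 (-5.80 ± 0.58), Efemp1 (-5.79 ± 0.34), the proteoglycan gene Dcn (-5.40 ± 0.97), Penk (-5.35 ± 0.67), the thrombomodulin gene Thbd (-5.25 ± 0.63), Nov (-5.15 ± 0.77) and the shared gene Hba-a2 (-5.10 ± 1.06). Immediate early genes were lower in 8 of 22 (16 adjusted over the list alone; camera adjusted p = 5.16e-06, and adjusted p = 0.692 with an estimated correlation), among them Klf2 (-2.69 ± 0.41) and Cyr61 (-2.98 ± 0.57). The medians of this list were 12.43, 12.18 and 9.29 in PDGFRa-GFP replicates 1, 2 and 3, so that the third replicate lay in the range of the PLP-GFP libraries. MHC, complement and interferon genes were lower in 5 of 20 (8 adjusted over the list alone; camera adjusted p = 4.70e-04, and adjusted p = 0.473 with an estimated correlation), with the complement gene C4b (shared) at -2.25 ± 0.32. Microglial markers were lower in 2 of 16 (2 adjusted over the list alone; camera adjusted p = 0.0216, and adjusted p = 0.909 with an estimated correlation), C1qc (-1.40 ± 0.40) and Tmem119 (-0.85 ± 0.24), each no longer called in 5 of the 6 fits that left out a library.

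Among oligodendrocyte genes, newly formed markers were lower in 5 of 23 (5 adjusted over the list alone; camera adjusted p = 0.0112, and adjusted p = 0.909 with an estimated correlation), with Tmem163 at -1.68 ± 0.22. Markers of mature states were lower in 5 of 24 (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00922, and adjusted p = 0.473 with an estimated correlation), such as Klk6 (-1.51 ± 0.24) and Sec11c (-1.04 ± 0.15). Oxidative phosphorylation subunits were lower in 12 of 28 (21 adjusted over the list alone; camera adjusted p = 7.01e-07, and adjusted p = 0.692 with an estimated correlation), such as Sdhc (-1.07 ± 0.23). Their median log2 fold change was -0.60, and -0.17 with the length trend removed. That correction ended the calls of the mature state list (camera adjusted p = 0.179) and the microglial list (0.179), whose p-values over the alternatives with the preset correlation ran from 2.09e-04 to 0.227 and from 7.00e-04 to 0.248. Those of the newly formed list ran from 2.92e-06 to 0.281 and those of the MHC, complement and interferon list from 5.43e-05 to 0.125, with the call lost in 3 and 1 of 19 alternatives. Without PDGFRa-GFP replicate 1, 4 lists were called in place of 7.

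The other 17 tested lists had camera adjusted p-values from 0.0514 to 0.973. Myelin sheath genes fell in 3 of 27, Pllp (-0.74 ± 0.16), Opalin (-0.75 ± 0.18) and Mog (-0.54 ± 0.13), with a list median of 0.00. Of the 16 progenitor markers, Pdgfra fell and Lrrn1 rose (0.55 ± 0.14). The calls of Lrrn1, Opalin and Mog were each lost in 3 of the 6 fits that left out a library. Adjusted over the list alone 2 fell and 1 rose, and the list had a median log2 fold change of -0.32 (camera adjusted p = 0.493). Glycolysis genes fell in 6 of 22 and rose in 2 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0514), where Eno2 (2.04 ± 0.24) and Pfkl (1.46 ± 0.15) rose and Eno1 (-0.88 ± 0.13, shared) fell. The astrocyte markers F3 (-3.27 ± 0.64) and Gjb6 (-3.29 ± 0.66) fell out of 18 (2 adjusted over the list alone), and the endothelial marker Cldn5 (5.26 ± 1.13) rose while Itm2a (-2.71 ± 0.60) fell.

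NDRG1-eGFP was then compared with PDGFRa-GFP, the outer groups of the labelled series. Cholesterol synthesis enzymes were higher in NDRG1-eGFP cells in 10 of 20 and lower in 1 (12 and 2 adjusted over the list alone), as in Sqle, the squalene epoxidase gene (1.07 ± 0.14, SE, n = 3), Hmgcs1 (0.92 ± 0.15) and Sc5d (0.83 ± 0.11). Elovl1, a very long chain fatty acid elongase gene, was also higher (0.97 ± 0.13). Lower were the progenitor proteoglycan gene Vcan (-4.04 ± 1.18), the differentiation inhibitor Id4 (-2.80 ± 0.55), the transcription factor genes Tcf7l2 (-0.74 ± 0.14), Zfp488 (-1.11 ± 0.25, shared) and Myrf (-0.69 ± 0.18), Rap2a (-1.64 ± 0.28), Hcn2 (-2.42 ± 0.35) and the bicarbonate transporter gene Slc4a4 (-3.99 ± 0.50). Vcan and Myrf each lost their call in 4 of the 6 fits that left out a library. As lists, progenitor markers rose in 1 of 16 and fell in 1 (camera adjusted p = 0.308). Newly formed markers rose in 2 of 23 and fell in 4 (camera adjusted p = 0.0762). Oligodendrocyte transcription factors rose in 1 of 15 and fell in 3, and myelin sheath genes rose in 3 of 27 and fell in 1 (camera adjusted p = 0.276 for both). Fibroblast-like markers and immediate early genes did not pass limma's adjusted threshold in any member (0 of 11 and 0 of 22, also adjusted over the list alone), with medians of -0.36 and 0.21.

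The highest fold changes that met the naming rule, with its minimum level, were those of H2-T10 (8.34 ± 0.67, shared), the lysozyme gene Lyz2 of microglia and macrophages (3.48 ± 0.30, 15.4% shared), the MHC class II gene H2-Ab1 (2.75 ± 0.63), Rab7b (1.67 ± 0.16), Gpr176 (1.53 ± 0.38, call lost in 3 of 6 fits that left out a library), Il12a (1.51 ± 0.26), the claudin gene Cldn14 (1.45 ± 0.32), the sialyltransferase gene St8sia5 (1.44 ± 0.23), Ly6g6e (1.44 ± 0.28) and Acy3 (1.41 ± 0.24, shared). Microglial markers were higher in 3 of 16 (6 adjusted over the list alone; camera adjusted p = 0.0567), including Trem2 (1.51 ± 0.45, call lost in 4 of 6 such fits). Over the alternatives with the preset correlation, the camera adjusted p of this list ran from 0.001675 to 0.165, and 10 of 19 called it. The 10 lowest that met the rule were mt-Atp8 (-9.24 ± 0.42) and the shared genes Hba-a1 (-9.86 ± 0.87), mt-Co2 (-9.15 ± 0.34), mt-Atp6 (-8.41 ± 0.41), Tuba1b (-7.92 ± 0.40), Ubb (-7.75 ± 0.22), Rpl24 (-7.46 ± 0.28), mt-Co3 (-7.45 ± 0.45), Rps23 (-7.39 ± 0.35) and Rpl9 (-7.34 ± 0.32).

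Here 1207 genes were higher and 1176 lower (limma). The median of all genes was 0.14, and after recentring on the median ratio 591 were higher and 1362 lower, so that the higher share of the calls moved from 50.7% to 30.3%. With the length trend removed, 513 were higher and 1123 lower, 1332 of them among the 2370 earlier calls with the same direction. Without shared genes 662 genes were lower. The number higher was 2804 without PDGFRa-GFP replicate 3, 655 and 720 without PDGFRa-GFP replicate 1 and 2, and 447, 480 and 754 without NDRG1-eGFP replicate 1, 2 and 3. The number lower was 1817 without PDGFRa-GFP replicate 3.

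Camera called 0 of 24 lists in this comparison, with 6 at an unadjusted p under 0.05, 0 with an estimated correlation, and 6 by fry, which tests each list by itself. Without shared genes, camera called 5 lists: newly formed markers and pathway inhibitors of differentiation and ion channels lower, and cholesterol synthesis and microglial markers higher. Leaving out PDGFRa-GFP replicate 1, 2 or 3 gave 1, 2 and 4 called lists, and leaving out NDRG1-eGFP replicate 1 or 2 gave 5 and 2. Mature state markers rose in 7 of 24 and fell in 2, actin assembly genes fell in 6 of 21, hypoxia response genes fell in 5 of 19 and rose in 1, and chromatin enzymes fell in 6 of 25 and rose in 3, with the shared gene Hdac1 at -1.55 ± 0.12. Glycolysis genes fell in 6 of 22 and rose in 2, and fatty acid and sphingolipid enzymes rose in 5 of 26 and fell in 1.

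The genes were also sorted by their course over both steps, from PDGFRa-GFP through PLP-GFP to NDRG1-eGFP. Most genes called at both steps reversed direction: 750 genes were highest in PLP-GFP cells and 770 lowest there. Fcho1, Pxdn, Dlk2, Pcdhga4 and Zrsr1 were the named genes with a peak in PLP-GFP cells, with log2 fold changes to NDRG1-eGFP cells of -5.14 ± 1.06, -4.38 ± 0.43, -3.48 ± 0.38, -3.02 ± 0.37 and -2.42 ± 0.18 (SE, n = 3). Mgp, Slc47a1, Fxyd5, Penk and Efemp1 were the named genes with a trough. Falling at both steps were 74 genes, and 33 with the length trend removed. Of the 74, 71 were shared, against 9.09% of all annotated genes tested, and 37 encoded ribosomal proteins, of 79 tested. The count of falling genes was 5 and 7 without PLP-GFP replicate 2 and 3, 115 and 19 without PDGFRa-GFP replicate 1 and 2, and 48 without NDRG1-eGFP replicate 2. The named genes among the 74 were the ribosomal protein genes Rpsa and Rps2, Actg1 and Hmgn2, all shared, and the mitochondrial leucyl-tRNA synthetase gene Lars2 (-1.40 ± 0.41 and -3.95 ± 0.41), whose fall at the earlier step lost its call in 4 of 6 fits that left out a library. Lars2 averaged 19.33, 17.93 and 13.98 in PDGFRa-GFP, PLP-GFP and NDRG1-eGFP libraries, far above the median of all genes. A single gene rose at both steps, the shared gene H2-T10, with means of 0.93, 3.92 and 9.27. The count of rising genes was 0 without PLP-GFP replicate 2 or 3, and 2 and 14 without PDGFRa-GFP replicate 1 and 3.

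Independent lists of the same sizes would share 212 genes highest and 252 lowest in PLP-GFP cells, 214 falling and 250 rising at both steps. Both steps use the same PLP-GFP libraries, so part of the excess may come from these shared libraries. This was not tested with separate PLP-GFP libraries for each step. The covariance of the fold changes of both steps was -0.57, against a mean of -0.08 in 100 simulations of unchanged groups, a difference of -0.49. Their correlation was -0.620, against a mean of -0.50 in the simulations, a difference of -0.119. The covariance and the correlation are on different scales. With the length trend removed, 302 genes were highest and 501 lowest in PLP-GFP cells. Without PLP-GFP replicate 2 or 3 the highest counts were 84 and 130 and the lowest counts 171 and 207, and without PDGFRa-GFP replicate 2 they were 324 and 333. Without shared genes 3 genes fell at both steps, Capns1, Lars2 and Rps24, named after their values were seen.

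Fold changes in all comparisons followed transcript length and, most strongly where NDRG1-eGFP was compared, shared sequence. Among the 5088 genes with no shared window and a mean of at least 8, the Spearman correlation of log2 fold change with length across genes, which are not independent replicates, was -0.661 for NDRG1-eGFP against PLP-GFP, 0.574 for PLP-GFP against PDGFRa-GFP and -0.484 for NDRG1-eGFP against PDGFRa-GFP. The median log2 fold change of NDRG1-eGFP against PLP-GFP went from 0.76 for 901 genes of 1 to 2 kb to -0.67 for 215 genes over 8 kb. Of 79 ribosomal protein genes, 74 were shared, and 70 were lower in NDRG1-eGFP than in PDGFRa-GFP cells. Against PLP-GFP, 60 were lower and 4 higher, with a median of -1.98, while the 5 that were not shared had a median of 0.81. In PLP-GFP against PDGFRa-GFP, 49 were lower and 0 higher, with a median of -0.85, and of -0.92 for the same 5. The 44 genes with over 50 percent shared windows had medians of -1.49 against PLP-GFP and -1.43 against PDGFRa-GFP, and of -0.18 between those 2 groups. In PLP-GFP against PDGFRa-GFP the 132 genes with 25 to 50 percent shared windows had a median of -0.32, with 24.2% called lower and 0.758% higher.

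**Figure D3:**
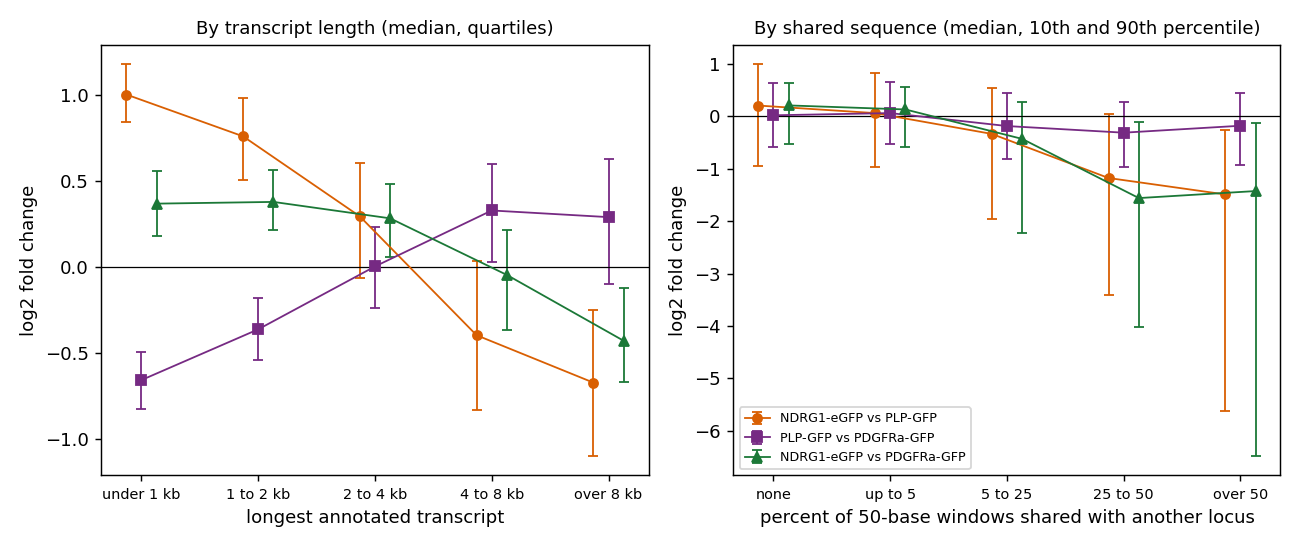
Log2 fold change (vertical axes) by length of the longest annotated transcript (left, medians with quartiles) and by percent of shared 50-base windows (right, medians with 10th and 90th percentiles) for the 3 comparisons (colours). Genes of 1 to 2 kb sit at a median of 0.76 in NDRG1-eGFP against PLP-GFP and at -0.36 in PLP-GFP against PDGFRa-GFP, and genes with over 50 percent shared windows sit at -1.49 and -1.43 in both NDRG1-eGFP comparisons.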

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

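Alternatives are given where a count or a number of called lists moved by over 1.5 times, in the order of the comparisons NDRG1-eGFP against PLP-GFP, PLP-GFP against PDGFRa-GFP and NDRG1-eGFP against PDGFRa-GFP. No named gene that was called changed sign and no called list changed direction under any alternative. The balance of calls did change for NDRG1-eGFP against PLP-GFP, with 2555 higher and 2789 lower after recentring on the median ratio and 1798 and 1978 with the length trend removed. For NDRG1-eGFP against PDGFRa-GFP it moved from 1207 higher and 1176 lower to 591 and 1362 after recentring. For PLP-GFP against PDGFRa-GFP it moved from 957 and 965 to 903 and 782 without shared genes, and to 402 and 646 with the length trend removed. Medians of some lists that were not called changed sign with the length trend removed, such as the progenitor list from -0.15 to 0.17 for NDRG1-eGFP against PLP-GFP. The cause of a movement was not tested unless the alternative itself shows it.

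A replicate block gave 338 higher and 384 lower for PLP-GFP against PDGFRa-GFP and 457 higher for NDRG1-eGFP against PDGFRa-GFP, with 1 list called there. With the block, 0 genes rose and 19 fell at both steps, 292 were highest and 325 lowest in PLP-GFP. Libraries with the same replicate number correlated at -0.23 to 0.09 after group means were removed and others at -0.13 to 0.23, so pairing was not used.

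With an absolute log2 fold change of at least 1, the counts higher and lower were 936 and 1350, 284 and 353, and 159 and 657, with 10 falling at both steps, 210 highest and 278 lowest in PLP-GFP. With an adjusted p under 0.01, 1816 were higher for NDRG1-eGFP against PLP-GFP, then 121 and 171, and 240 and 659, with 0 rising, 7 falling, 110 highest and 153 lowest.

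With the length trend removed, 1798, 402 and 513 genes were higher, 3 rose and 33 fell at both steps, 302 were highest and 501 lowest, and 5 lists were called for NDRG1-eGFP against PLP-GFP. With shared genes left out as well, counts were 1675 and 1347, 361 and 570, and 339 and 483, with 0 rising, 4 falling, 269 highest and 479 lowest, and 4, 4 and 5 lists. Without shared genes alone, 662 were lower for NDRG1-eGFP against PDGFRa-GFP, 0 rose and 3 fell at both steps, and 5 lists were called. A mean of at least 8 gave 0 rising and 5 lists for NDRG1-eGFP against PLP-GFP.

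Fits of only the groups compared gave 552 and 514 for PLP-GFP against PDGFRa-GFP and 318 and 724 for NDRG1-eGFP against PDGFRa-GFP, with 0 rising, 38 falling, 487 highest, 408 lowest and 1 list. Recentring on the median ratio gave 591 higher for NDRG1-eGFP against PDGFRa-GFP and 1 list, and 592 and 1 without the myelin list and the 20 most abundant genes. Without NDRG1-eGFP replicate 2 and PDGFRa-GFP replicate 3 together, 1525 were higher for PLP-GFP against PDGFRa-GFP and 2262 for NDRG1-eGFP against PDGFRa-GFP, 15 rose at both steps, and 2 lists were called. With an estimated correlation camera called 0 lists in each comparison, and fry called 14, 3 and 6.

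Leaving out 1 library gave 2114 to 2633 higher and 1847 to 2313 lower for NDRG1-eGFP against PLP-GFP, 92 to 1449 and 186 to 1340 for PLP-GFP against PDGFRa-GFP, and 447 to 2804 and 836 to 1817 for NDRG1-eGFP against PDGFRa-GFP. It gave 0 to 14 rising, 5 to 115 falling, 84 to 1076 highest and 171 to 1058 lowest, and 7 to 8, 4 to 7 and 0 to 5 lists.

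Count-based size factors, the DESeq2 Wald test and voom were not run, since they need counts. The alternative with no filter equals the fit itself, since the filter removed 0 genes.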

Other observations

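Other genes of the mitochondrial genome differed widely in their fold change in the NDRG1-eGFP libraries. Against PDGFRa-GFP, mt-Cytb (-0.12 ± 0.22, SE, n = 3), mt-Nd1 (-0.24 ± 0.34), mt-Nd6 (-0.37 ± 0.27), mt-Nd2 (-0.63 ± 0.27, 8.19% shared), mt-Nd5 (-0.65 ± 0.31, 7.61% shared) and mt-Nd4 (-0.09 ± 0.26, 62.2% shared) were not called by limma. The genes mt-Nd4l (-7.91 ± 0.40, 98.8% shared), mt-Nd3 (-3.26 ± 0.53, 98% shared) and, less far, mt-Co1 (-1.25 ± 0.29, 51.1% shared) fell.

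Y-linked genes differed between libraries of 1 group. Ddx3y had values of 9.26, 12.43 and 0.32 in PDGFRa-GFP replicates 1, 2 and 3, 13.23, 1.57 and 1.63 in PLP-GFP replicates, and 8.64, 1.82 and 7.33 in NDRG1-eGFP replicates, and Eif2s3y was below 2 in the same 4 libraries. Ddx3y, Eif2s3y, Kdm5d and Uty were not called in any comparison (limma), and Xist had no row. Each group held libraries with high and with low Ddx3y values. That argues against 1 animal for all libraries of a group, and sex was not a term of the fit. Of the 210 genes with a peak and 278 with a trough in PLP-GFP cells of at least 1 at both steps, 265 with a known position also met the level and overlap limits of the naming rule. Among these, 22 pairs of neighbours lay within 100 kb, against a mean of 11.5 and a highest count of 26 in 10000 random sets of as many genes, drawn from those with a mean of at least 8 without the other limits (permutation p = 0.00390). In 12 pairs both genes changed in the same direction from PDGFRa-GFP to PLP-GFP and in 10 in opposite directions. Among the 22 pairs were Pcdhga4 with Pcdhga5, Pcdhga5 with Pcdhga6 and Pcdhga6 with Pcdhga11 on chromosome 18, all ending at base 37841873. These overlapping genes are not separate loci, so the permutation p does not measure neighbouring of separate genes alone. Dusp26, Rnf122 and Fut10, between 31089471 and 31261738 on chromosome 8, were all lower in PLP-GFP than in PDGFRa-GFP cells (-4.20, -2.10 and -1.37). Hddc3, Man2a2 and Furin, between 80343104 and 80405436 on chromosome 7, were all higher (2.11, 1.07 and 1.04).

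The tests of mitochondrial sets, progenitor markers and fibroblast-like markers below were chosen after their results were seen, and the length and sharing corrections were also added then. A first pattern was the low value of genes with near-identical copies in NDRG1-eGFP libraries. Some shared genes went the other way. Against PLP-GFP, H2-T10 (33.3% shared), Hist1h2al (67.6%) and Hist2h2aa2 (100%) had log2 fold changes of 5.36, 4.24 and 4.24. Of the 44 genes with over 50 percent shared windows given above, 65.9% were called lower and 2.27% higher in that comparison. Lower ribosomal protein expression was tested on the 5 ribosomal protein genes with few shared windows, whose median was -0.10 (95% bootstrap interval -1.98 to 0.34), too wide to decide. The length trend was argued against as the whole cause, since genes with over 50 percent shared windows kept a median of -1.69 (-2.60 to -1.17) after its removal. A candidate explanation is that reads matching several places were handled differently in these libraries: mitochondrial mRNAs with at least 90 percent shared windows had a median 7.41 below those with under 10 percent (difference -7.41), although mt-Nd4 with 62.2% did not fall (-0.09), and mt-Atp8, with no shared window among annotated transcripts, did. Handling and cell type coincide with the group, so they cannot be told apart here.

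The dependence of fold changes on transcript length was the second pattern. A change of short ribosomal and respiratory chain genes alone was argued against, since the Spearman correlation with length for PLP-GFP against PDGFRa-GFP was 0.565 without them. A length dependence of the PLP-GFP libraries as a whole stays open: the lowest correlation over 5 classes of mean level, 0.436 among genes in no list, describes the trend again and tests no cause, and the correlation of -0.484 for NDRG1-eGFP against PDGFRa-GFP involves no PLP-GFP library. Library preparation or processing cannot be told apart from cell type, because the labels give no batch, although the correlation of a library's deviations with length already differed by up to 0.730 within the PDGFRa-GFP group. It was 0.370, 0.0688 and -0.361 in PDGFRa-GFP replicates 1, 2 and 3, 0.536 to 0.660 in PLP-GFP libraries and -0.665 to -0.432 in NDRG1-eGFP libraries.

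As the third pattern, Pdgfra was higher in PDGFRa-GFP than in PLP-GFP libraries. The length trend was argued against, since the log2 fold change was -4.27 after its removal (-5.22 to -3.31 for 1 standard error either side). More fibroblast-like cells in the PDGFRa-GFP libraries may account for it, as the 11 measured fibroblast-like markers, none of which is in another list, had a median of -3.71 (95% bootstrap interval -4.95 to -3.23), and Mgp and Col1a2 reached 11.42 and 10.16. The sort on GFP would not remove fibroblasts that express Pdgfra. That reason does not cover the NDRG1-eGFP libraries, sorted on another reporter, which held these markers at a similar level. Against PDGFRa-GFP the list had a median of -0.36 there, with 0 of 11 members called by limma. More progenitor cells stay open as the biological explanation from the labels, since the 15 other progenitor markers had a median of -0.31 (-0.73 to 0.55). Most progenitor markers lay at low values, with 5 of 16 at a mean of at least 8.

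Other splits of the 6 libraries of each comparison into 3 and 3 were counted with limma. For NDRG1-eGFP against PLP-GFP the real split was the 1 of 10 that called as many as 5460 genes, and the highest other split called 0. At an unadjusted p under 0.05 the real split had 6280 genes and the highest other 206. For PLP-GFP against PDGFRa-GFP it was 1 of 10 with 1922 genes, the highest other 0, with 3981 and 1025 unadjusted. For NDRG1-eGFP against PDGFRa-GFP it was 1 of 10 with 2383 genes, the highest other 0, with 4106 and 2595 unadjusted. With 10 splits a share under 0.05 is not possible. Each other split put libraries of both groups on either side, so the group difference entered its spread. Few calls there were therefore fixed largely in advance, and these splits cannot decide whether the calls arose by chance.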
